A study of Homo sapiens with 9 samples.

How the data were processed

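RNA abundance was measured in 9 libraries, 3 from each of 3 groups. The groups were control M14 cells (a metastatic melanoma line), M14 cells in which the RAD6B gene (UBE2B) had been targeted with CRISPR/Cas9, and HEMa-LP cells (labelled as normal epidermal melanocytes in primary culture). Per the labels' protocols, total RNA was DNase-treated and libraries were made with the Lexogen QuantSeq FWD kit. That kit primes on poly(A) and sequences the 3' end of each transcript, so each read is a tag and transcript length plays little part in the level of a gene. The labels also gave different culture conditions. HEMa-LP cells grew in a dermal cell medium with growth supplements, and both M14 groups grew in DMEM/F12 with serum.

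The authors deposited raw read counts per gene symbol in 2 tables, of which 1 held the M14 groups and 1 held all 3 groups. The M14 columns of both tables were identical. Per the submitters' processing notes, CASAVA 1.8.2, FastQC, STAR, HTSeq and edgeR were used with genome build hg38. Their order and settings, the gene annotation and the strand setting of the counting are not given in the sources used here. The series design states that M14 samples were run in duplicate. Each had 1 column of counts, and whether the runs were merged or 1 was taken is not given in the sources used here. The authors also deposited 2 tables of their own comparisons, with log2 fold changes and with p-values and false discovery rates, whose model and filter are not given in the sources used here. A stray header line inside 1 of these tables was skipped. Values from them are named as the authors' deposited table wherever they appear. Every unit named here was checked against the values of its column.

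Each count table had 27470 genes, of which 7700 had no count in any library. Before any test 152 genes were removed, because the HEMa-LP cells came from a person. These were XIST, TSIX, Y-linked genes and genes whose level mostly reports a germline deletion or haplotype, among them the HLA class I and class II genes. The 27318 genes left were used for library sizes and tests. By symbol, 25002 of the 27470 genes (91.0%) were found in the GENCODE release 29 annotation of hg38, from which all coordinates were taken, and 25201 (91.7%) matched a RefSeq symbol. Older symbols were kept as the tables gave them.

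Levels are CPM, which relate each count to the total of its library, computed here from the deposited counts, scaled by library size times the TMM factor, and are given as mean ± SD over 3 libraries. Genes were kept for a comparison with edgeR's filterByExpr, and only the libraries of the groups compared entered each fit. Each comparison used edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with TMM normalization and no replicate block. A gene passed when its Benjamini-Hochberg adjusted p was under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

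The gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. For each of 30 lists the members that passed were counted with the p adjusted over all genes tested, and again adjusted over the list alone. A list of at least 5 tested members was also tested with limma's camera, which compares its members with all other genes. It was run on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and was adjusted over the lists tested. A camera run with the correlation estimated for each list, and fry, were alternatives. The text names UBE2B and UBE2A, a fixed set of 7 Wnt and melanocyte genes, and up to 4 members of each list described, taken by smallest adjusted p among members that passed at 5 CPM or more. It also names, per comparison, the 8 largest rises and 8 largest falls in fitted log2 fold change among protein-coding or HGNC-named genes. Those had to pass at 20 CPM or more in the higher group, with no overlap between the groups' libraries. A list was described where camera called it or where it was one of the Wnt, RAD6, pigmentation, lineage, cell cycle, keratinocyte or fibroblast lists.

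Depth differed between groups. Control M14 libraries held 6024057 to 6752831 counts, knockout-labelled libraries 5293452 to 6521201 and HEMa-LP libraries 1019614 to 1212873. A count of 0 over the 3 libraries of a group allowed a level of up to 3 counts, which was 0.155 CPM in control M14, 0.166 CPM in the knockout-labelled group and 0.931 CPM in HEMa-LP. Folds against a group at 0 were computed against that floor and are lower bounds. Where a group held 1 to 3 counts, the ratio is given with an exact 95% counting interval. Intervals and floors cover counting error only.

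The test was checked on simulated counts with 200 changed genes, drawn from the means and library sizes of each comparison. Of genes changed by 2-fold, 78% were recovered for knockout against control M14, 76% for control M14 against HEMa-LP and 68% for the knockout against HEMa-LP. For 1.5-fold changes the shares were 52%, 44% and 28%. At 4-fold they were 100%, 100% and 96%. False calls made up 3.53%, 4.76% and 1.35% of the calls. These shares come from a single draw per comparison with few changed genes, equally many up and down. In the data most tested genes passed, so the shares need not hold there.

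Both comparisons with control M14 share its 3 libraries. The covariance of their fold changes was therefore set beside 100 simulations of unchanged groups against those libraries. Alternatives were DESeq2 size factors, the DESeq2 Wald test, limma-voom, no low-count filter, a filter of 5 CPM in 3 libraries, 1 fit over all 9 libraries, the replicate number as a block, robust spread estimates, a minimum absolute log2 fold change of 1, and leaving out each library in turn. After the data were seen, 2 were added: thinning M14 libraries to the depth of the HEMa-LP libraries, and leaving out pseudogenes, genes with an annotated pseudogene copy and mitochondrial rRNA genes. Every other split of each pair of groups into 3 and 3 libraries was also tested.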

Results

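Transcript abundance was compared between control M14 cells, M14 cells labelled as RAD6B knockout, and HEMa-LP cells, labelled as melanocytes, with 3 libraries in each group. RAD6B, encoded by UBE2B, is an E2 ubiquitin-conjugating enzyme that acts in DNA damage tolerance and histone H2B ubiquitination. The series asks what RAD6B contributes to canonical WNT signalling in melanoma. Total counts ran from 6024057 to 6752831 in control M14 libraries, from 5293452 to 6521201 in knockout-labelled libraries and from 1019614 to 1212873 in HEMa-LP libraries. Within groups, log CPM values correlated across genes at Pearson's r of 0.959 to 0.985. Between groups r was 0.879 to 0.885 for control M14 and the knockout-labelled libraries, 0.643 to 0.653 for control M14 and HEMa-LP, and 0.662 to 0.671 for the knockout-labelled libraries and HEMa-LP. Libraries of a group differed by more than sampling noise, with a chi-square per gene of 1.78 to 5.50, and all 9 were kept as separate replicates. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries. A single knockout-labelled line was compared with its parental line, and the labels do not say how many clones it came from.

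UBE2B, the targeted gene (chromosome 5, 134371179 to 134391992, plus strand, hg38), was detected in every library. Its level was 126, 111 and 120 CPM in the control M14 libraries, 138, 149 and 172 CPM in the knockout-labelled libraries, and 60.8, 81.9 and 68.8 CPM in HEMa-LP. The knockout-labelled group lay above control M14 by 0.37 on the log2 scale (SE 0.09, edgeR adjusted p = 4.7e-04). Both M14 groups exceeded HEMa-LP, by 0.72 (adjusted p = 2.0e-06) for control M14 and by 1.11 (adjusted p = 4.5e-10) for the knockout-labelled group. UBE2A (chromosome X, 119574467 to 119591083), which encodes the close paralog RAD6A, fell from 105 ± 1.96 to 63.3 ± 4.45 CPM, a log2 change of -0.73 (adjusted p = 2.7e-08). The last 500 bases of the coding transcripts of UBE2A and UBE2B shared at most 25 identical bases in a row. The position of the edit is not given in the sources used here, and a 3' tag outside the edited part reports a transcript whether or not it encodes protein. The UBE2B level therefore neither shows nor excludes the knockout, it goes against a simple loss of transcript, and the direction of every difference below rests on the labels.

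In libraries labelled knockout, interferon-stimulated genes rose together, while genes of DNA replication, mitosis and cholesterol synthesis fell together. IFI6, an interferon-induced mitochondrial protein (chromosome 1, 27666061 to 27672218), went from 170 ± 21.6 to 5096 ± 234 CPM, a 29.9-fold rise (log2 4.91, SE 0.08, adjusted p = 8.6e-40). IFI27 rose from 0.929 ± 0.151 to 170 ± 6.62 CPM, and IFI44L from 0.300 ± 0.243 to 238 ± 8.85 CPM. IFITM1, a membrane protein that restricts viral entry, rose from 6.35 ± 1.63 to 210 ± 3.63 CPM. IFITM1 lies inside the annotated span of IFITM2 and resembles IFITM2 and IFITM3, so its reads may have been divided among them by the counting. Of 39 tested interferon response genes 38 rose, 1 fell and none failed to pass, with the same counts adjusted over the list alone. Their median log2 change was 2.81, and camera placed the list above other genes (adjusted p = 1.0e-15, and adjusted p = 0.00713 with an estimated correlation).

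The replication machinery was lower in the knockout-labelled libraries. CDC45, a subunit of the replicative helicase, fell from 89.0 ± 3.62 to 5.64 ± 1.70 CPM (log2 -3.95, adjusted p = 3.8e-24). MCM5 and MCM7, which belong to the same helicase, changed by -3.19 and -2.28, and RRM2, the regulated subunit of ribonucleotide reductase, by -3.45. Of 42 tested replication and S phase genes none rose and 41 fell, over all genes tested and adjusted over the list alone, with a median of -1.92 (camera adjusted p = 2.8e-15, and adjusted p = 0.00713 with an estimated correlation). Of 42 genes of G2 and mitosis 38 fell and 1 rose, again with the same counts adjusted over the list alone. Their median was -2.24 (camera adjusted p = 2.8e-15, and adjusted p = 0.00713 with an estimated correlation). AURKB, a kinase of the chromosomal passenger complex, dropped from 389 ± 28.8 to 52.1 ± 5.46 CPM. BIRC5 (survivin), which belongs to the same complex, dropped from 231 ± 13.0 to 28.8 ± 3.37 CPM. UBE2C, an E2 enzyme of the anaphase-promoting complex, changed by -2.60 and PRC1, a spindle midzone protein, by -2.62.

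Genes of the Fanconi pathway and homologous recombination fell more often than they rose. FANCD2 went from 92.9 ± 3.41 to 12.1 ± 4.37 CPM. FANCI and UBE2T, which with FANCD2 form the central ubiquitination step of the pathway, changed by -1.65 and -1.97. Of 28 tested members 15 fell and 4 rose, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.00464). That call was lost at adjusted p = 0.0810 with an estimated correlation. The RAD6 pathway and translesion synthesis list moved in both directions, with 10 of 23 members higher and 9 lower, also when adjusted over the list alone (camera adjusted p = 0.837). The translesion polymerase genes POLK and REV3L rose by 2.59 and 2.19, and HLTF, which extends PCNA ubiquitin chains, rose by 1.42. PCNA itself, the sliding clamp that RAD6 modifies, fell by 1.76 on the log2 scale.

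Cholesterol synthesis genes were lower in the knockout-labelled group. EBP, a sterol isomerase, fell from 310 ± 7.46 to 75.6 ± 9.38 CPM. HMGCS1 at the entry to the mevalonate pathway changed by -1.96 and the squalene epoxidase gene SQLE by -1.91. None of 22 tested members rose and 19 fell, with the same counts adjusted over the list alone (median -1.33, camera adjusted p = 9.9e-07, and adjusted p = 0.0311 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation fell by smaller amounts, 39 of 47 with 3 rising, again also when adjusted over the list alone (median -0.57, camera adjusted p = 9.9e-07). The camera call for oxidative phosphorylation was lost at adjusted p = 0.0810 with an estimated correlation. Among these, the ATP synthase subunit genes ATP5B and ATP5G3 changed by -1.55 and -1.46, and the cytochrome oxidase subunit genes COX5A and COX8A by -1.38 and -1.09. Several of these genes have pseudogene copies that can share reads.

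For the Wnt pathway, the question the series poses, single genes moved strongly in both directions. WNT1, a canonical Wnt ligand (chromosome 12, 48978453 to 48981676), was at 75.7 ± 6.24 CPM in control M14 and at 3 counts in all knockout-labelled libraries together (0.175 ± 0.188 CPM). The ratio was 457, with a counting interval of 156 to 2218. CTNNB1, which encodes beta-catenin (chromosome 3, 41194741 to 41260096), fell from 778 ± 9.47 to 488 ± 11.8 CPM (log2 -0.67, SE 0.07, adjusted p = 5.9e-12). The feedback inhibitor and standard pathway readout AXIN2 fell from 8.96 ± 1.14 to 0.944 ± 1.18 CPM (log2 -3.16, adjusted p = 8.6e-07). The T cell factor genes TCF7 and LEF1 changed by -3.22 and -0.92, and MYC by -0.94. APCDD1, itself an inhibitor of Wnt signalling, went from 9.12 ± 1.04 CPM to no count, at least 54.9-fold lower. CCND1, which encodes cyclin D1, was at 173 ± 6.20 and 158 ± 13.7 CPM (log2 -0.12, adjusted p = 0.199).

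**Figure D1:**
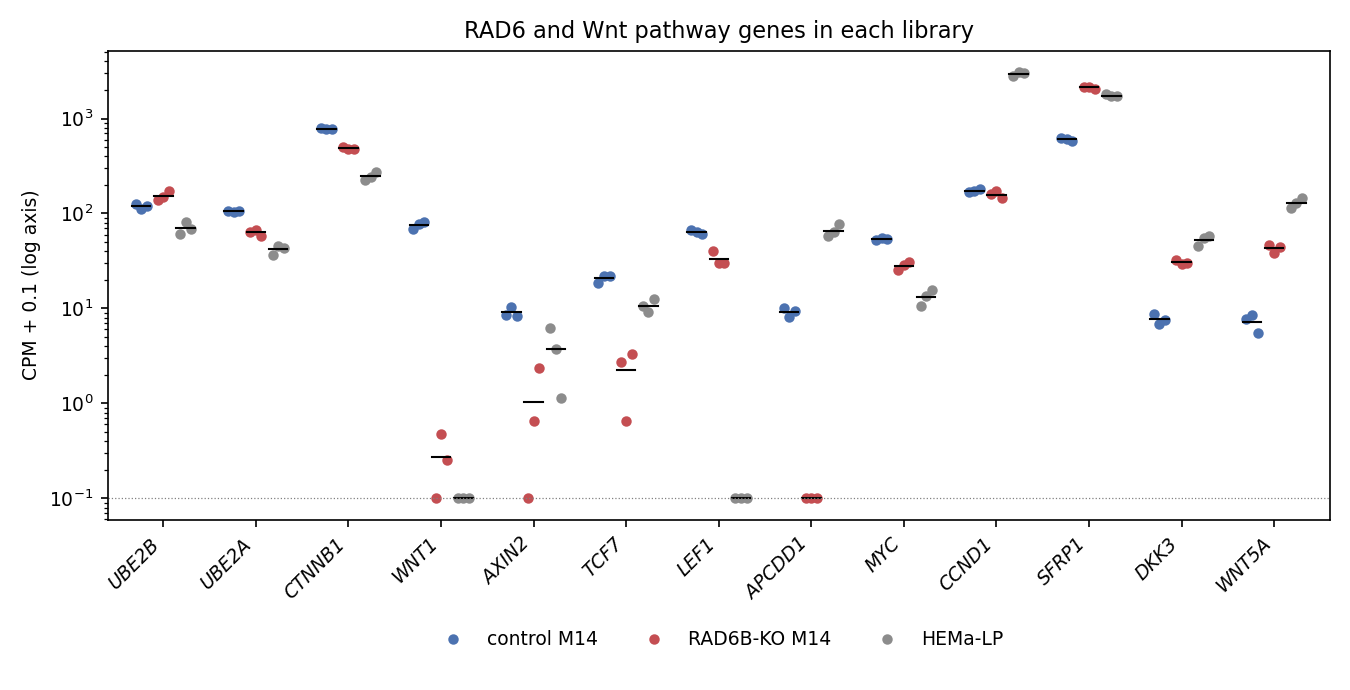
Levels of UBE2B, UBE2A and 11 Wnt pathway genes in each library, as CPM plus 0.1 on a log axis, for control M14, knockout-labelled M14 and HEMa-LP (points are libraries and black bars group means, n = 3). WNT1, AXIN2, TCF7 and APCDD1 sit lower in the knockout-labelled libraries than in control M14, while SFRP1, DKK3 and WNT5A sit higher.

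As a list, canonical Wnt targets did not move one way. Of 28 tested targets 12 rose, 11 fell and 5 did not pass, with the same counts adjusted over the list alone. JUN, a stress- and mitogen-responsive transcription factor gene, rose by 1.13, against the falls of AXIN2, TCF7, APCDD1 and BIRC5. The median log2 change was 0.18, the mean was -0.08, and camera did not separate the list from other genes (up, adjusted p = 0.915). The direction turned down with the 5 CPM filter (adjusted p = 0.752), without control M14 replicate 3 (0.956) and without knockout-labelled replicate 1 (0.923). The fry test of a shared direction, which does not compare the list with other genes, gave a lower level at adjusted p = 0.0286.

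Secreted Wnt antagonists and noncanonical ligands included large rises. SFRP1, which binds and sequesters Wnt proteins, rose from 605 ± 23.2 to 2124 ± 48.4 CPM, and DKK3, a member of the Dickkopf family, from 7.58 ± 0.991 to 30.4 ± 1.47 CPM. SFRP2 stood at 1 count in all control M14 libraries and at 8.27 ± 1.60 CPM in the knockout-labelled ones, a ratio of 160 with a counting interval of 28.2 to 6353. WNT5A, the main noncanonical ligand, rose from 7.08 ± 1.53 to 43.0 ± 4.08 CPM. PLCB1, a phospholipase C gene linked to these branches, rose by 2.33, the formin gene DAAM1 also rose, and RHOA fell by 0.79. The co-receptor gene LRP6 rose by 1.58 and PYGO1, a beta-catenin co-activator gene, by 2.24. Of 31 ligands, receptors and transducers 13 rose and 7 fell (camera adjusted p = 0.652), and of 15 antagonists 6 rose and 5 fell (adjusted p = 0.652). Of 28 noncanonical members 11 rose and 6 fell (adjusted p = 0.562). All 3 pairs of counts were the same adjusted over the list alone, and camera called none of these lists.

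Pigmentation genes were mostly lower in the knockout-labelled libraries, while the lineage regulators were divided. PMEL, which forms the fibrils of the melanosome (chromosome 12, 55954105 to 55973317), fell from 1525 ± 78.4 to 181 ± 22.3 CPM (log2 -3.07, SE 0.08, adjusted p = 2.6e-32). The melanosomal transporter gene SLC45A2 changed by -1.79 and the amino acid transporter gene SLC7A5 by -2.86, whereas HPS5, a gene of organelle biogenesis, rose by 2.20. The melanin synthesis gene DCT, singled out after its values were seen, also stood higher in the knockout-labelled than in the control M14 libraries. Its levels are given below with the comparisons to HEMa-LP. Of 32 tested members 23 fell and 5 rose, also when adjusted over the list alone (median -0.61, camera adjusted p = 1.6e-04). The call was lost at adjusted p = 0.0507 with an estimated correlation. MITF, the master regulator of the lineage, rose from 691 ± 15.2 to 876 ± 8.38 CPM (log2 0.35, adjusted p = 8.1e-06), and SOX10 fell from 446 ± 29.5 to 325 ± 18.3 CPM (log2 -0.45, adjusted p = 7.5e-07). SOX10 lies on chromosome 22, where the median tested gene fell further (medians of -0.69 and -0.91 in its blocks of neighbouring genes, described below). ZEB2 rose by 0.76, while TFAP2C changed by -0.45 and CDK2 by -1.72. Of 21 lineage regulators 8 rose and 11 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.652). CDK2 and PMEL overlap on opposite strands, and the strand setting of the counting is not given in the sources used here, so their reads may not have been told apart.

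Genes of the undifferentiated invasive state, the matrix and the mesenchymal programme rose more often than they fell. SERPINE2, a secreted protease inhibitor (chromosome 2, 223975112 to 224039319), rose from 4147 ± 220 to 37054 ± 2067 CPM, 8.94-fold (log2 3.17, adjusted p = 3.3e-38). ITGA3 and NT5E, which encode an integrin and the ectonucleotidase CD73, rose by 2.39 and 2.17. Of 26 invasive state genes 15 rose and 3 fell, median 0.85 (camera adjusted p = 0.00560, and adjusted p = 0.0810 with an estimated correlation). Of 38 matrix and adhesion genes 23 rose and 6 fell, with COL6A2 at 3.94, ITGB8 at 3.30, LAMA4 at 1.64 and FN1 at 1.58 (camera adjusted p = 7.0e-04, and adjusted p = 0.0883 with an estimated correlation). Of 24 epithelial-mesenchymal transition genes 14 rose and 4 fell, among them the repressor gene ZEB1 from 0.425 ± 0.397 to 16.1 ± 2.50 CPM (camera adjusted p = 0.0211, and adjusted p = 0.106 with an estimated correlation). These counts were the same adjusted over the list alone, and none of these camera calls held with an estimated correlation.

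Markers of other cell types were measured beside these groups. Of 12 tested fibroblast markers 8 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.101 with an estimated correlation). FBLN1 rose from 0.879 ± 0.748 to 30.7 ± 4.68 CPM, FBN1 by 1.99 and S100A4 by 1.51, and COL1A2 stood at 1 count in control M14 and 12.2 ± 1.46 CPM in the knockout-labelled libraries. Several of these genes also belong to the matrix and mesenchymal lists. Of 3 tested keratinocyte markers PERP rose by 0.28 (adjusted p = 0.00481) and KRT10 changed by -0.55 (adjusted p = 8.2e-06), also when adjusted over the list alone. PERP no longer passed without knockout-labelled replicate 3 (adjusted p = 0.0502), and over all alternatives its adjusted p ran from 0.00191 to 0.0502.

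More inflammatory and immediate early genes rose than fell in the knockout-labelled libraries. PTGS2, which encodes cyclooxygenase 2, rose from 9.56 ± 0.827 to 204 ± 9.03 CPM, and SOD2, the mitochondrial superoxide dismutase gene, from 31.0 ± 4.71 to 300.4 ± 16.5 CPM. The chemokine gene CCL2 rose from 0.198 ± 0.220 to 25.2 ± 0.332 CPM and the adhesion gene ICAM1 by 1.17. Of 23 tested NF-kB and cytokine genes 16 rose and none fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.00136, and adjusted p = 0.0810 with an estimated correlation). EGR1 rose from 19.3 ± 2.89 to 202 ± 20.7 CPM and IER3 from 1233 ± 107 to 4961 ± 289 CPM, with JUN and JUNB at 1.13 and 1.21. Of 22 immediate early genes 14 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.211 with an estimated correlation).

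**Figure D2:**
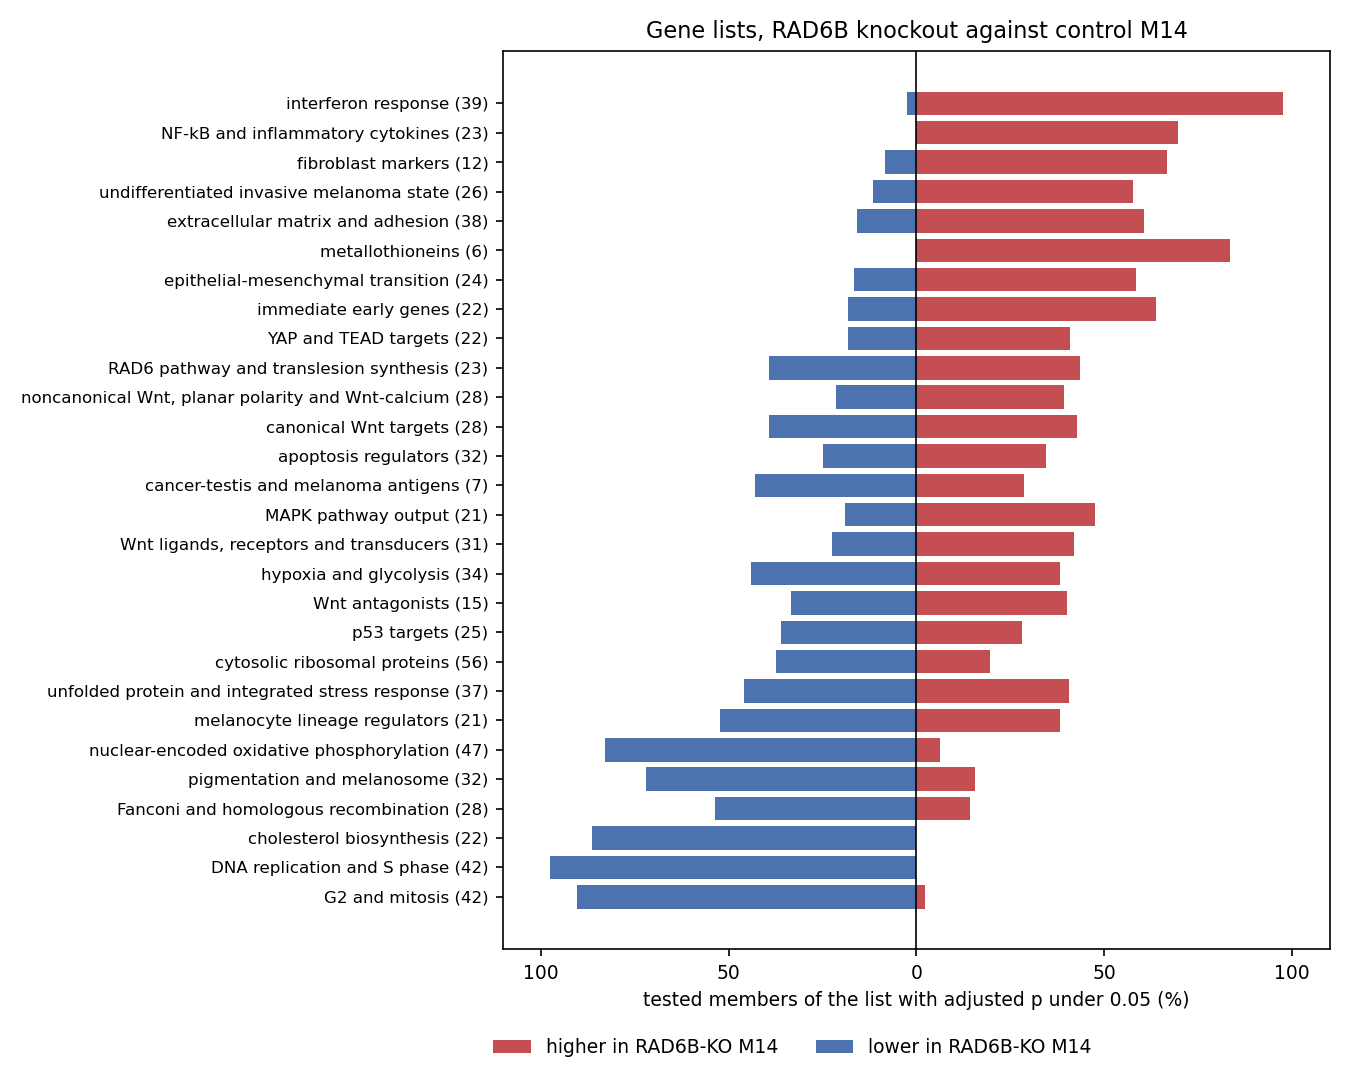
Share of tested members of each gene list (number tested in brackets) that passed at an adjusted p under 0.05, higher to the right and lower to the left, in the knockout-labelled against control M14 libraries (n = 3 per group). Interferon response genes lie almost wholly to the right (38 of 39) and DNA replication genes almost wholly to the left (41 of 42), with canonical Wnt targets near balance (12 and 11 of 28).

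The named genes with the largest changes included several that were close to absent in 1 of the groups. MUC15, a transmembrane mucin gene, had no count in control M14 and 42.8 ± 6.06 CPM in the knockout-labelled libraries, at least 276-fold higher. FAM171A1 and CBLN4 were likewise at least 211-fold and at least 131-fold higher. The neurotrophin gene BDNF had 1 count in control M14 and 63.4 ± 3.62 CPM in the knockout-labelled group, a ratio of 1226 with a counting interval of 220 to 48454. GPX3, a secreted glutathione peroxidase gene, also had 1 count in control M14 and reached 27.4 ± 2.35 CPM, while PLCXD3 and the atypical cadherin gene FAT3 rose by 9.08 and 8.95. Besides WNT1, the largest falls were TMEM163 (log2 -7.63), the P-cadherin gene CDH3 (-7.18), TCERG1L (-6.79), BAIAP2L2 (-4.89), the melanocyte channel gene TRPM1 (-4.78), TMEM204 (-4.65) and the Nogo receptor gene RTN4R (-4.60). CDH3 went from 358 ± 25.1 to 2.52 ± 2.17 CPM.

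Across the transcriptome, 7601 of 12061 tested genes (63.0%) passed, 3864 higher and 3737 lower in the knockout-labelled libraries. With a minimum absolute log2 fold change of 1, 3416 passed, 2025 higher and 1391 lower. For 8034 genes (66.6%) the 3 libraries of 1 group all lay above those of the other, where chance gives 10%. Camera called 13 lists, of which interferon response, replication, mitosis and cholesterol synthesis held with an estimated correlation. The authors' deposited table listed 9053 genes under the same false discovery rate, 7401 genes passed in both, all with the same sign, and the log2 fold changes correlated across genes at r = 0.999982.

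Fold changes also varied along the chromosomes. When 11267 tested autosomal genes were ordered by position and divided into 104 blocks of about 100, 7 block medians lay outside the range of 1000 shuffles of gene order, -0.48 to 0.56. Both blocks of chromosome 22 were low, at -0.69 and -0.91, as were the first block of chromosome 15 (-0.56) and the third of chromosome 11 (-0.48). The sixth block of chromosome 1 (0.65), the fourth of chromosome 7 (0.57) and the third of chromosome 8 (0.56) were high. Inside the shuffle range, medians also leaned one way over whole chromosomes. Every block of chromosomes 16, 19 and 20, and the later blocks of chromosome 15, had a negative median. Every block of chromosomes 4, 10, 13 and 14 had a positive one. Several low blocks were short, such as the first of chromosome 16 (46407 to 3880726, -0.45) and of chromosome 19 (281040 to 4655568, -0.42). Several high blocks were long, such as the third of chromosome 4 (86594315 to 139177218, 0.51) and of chromosome 8 (78666047 to 123042423). The low first block of chromosome 15 (22773063 to 50372202) was long too, and a relation to span was not tested. Among the genes named above, MCM5, CDC45, SOX10, BAIAP2L2 and RTN4R, which fell, and FBLN1, which rose, lie on chromosome 22. Of these, SOX10 fell by less than either block median of that chromosome. In the low block of chromosome 15 lie TRPM1, which fell, and FBN1, which rose. COX8A, which fell, lies in the low block of chromosome 11, and IFI44L, which rose, in the high block of chromosome 1.

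**Figure D3:**
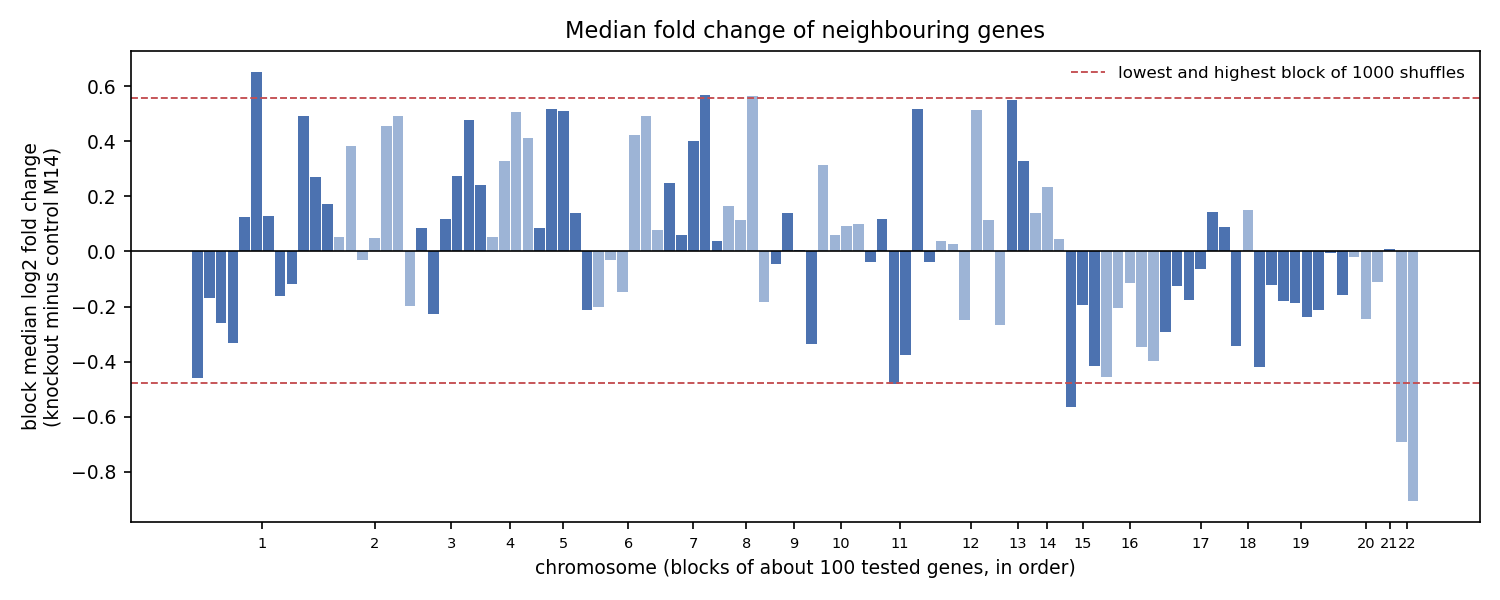
Median log2 fold change (knockout-labelled minus control M14) in 104 consecutive blocks of about 100 tested autosomal genes, ordered by chromosome, with dashed lines at the lowest and highest block median of 1000 shuffles of gene order. Both bars of chromosome 22 lie below the lower line, at -0.69 and -0.91.

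Control M14 cells were next compared with HEMa-LP cells, which are labelled as normal melanocytes. Cell type was confounded in this comparison with culture medium and with depth. Mitochondrial rRNA genes took 3.38 ± 0.206% of counts in control M14 and 3.44 ± 0.246% in the knockout-labelled libraries, but no count in HEMa-LP. The MTRNR2L genes, nuclear near-copies of the mitochondrial 16S rRNA, stood at 83.9 ± 0.161, 78.1 ± 7.45 and 6683 ± 395 CPM. Pseudogenes took 0.230%, 0.238% and 1.10% of counts. Genes with near-identical copies are therefore uncertain in every comparison with HEMa-LP.

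Pigmentation and lineage genes were far higher in control M14 than in HEMa-LP. DCT, a melanin synthesis enzyme gene, was at 1863 ± 50.4 CPM in control M14 with no count in HEMa-LP, at least 2001-fold higher. PMEL was at 1525 ± 78.4 against 4.05 ± 1.38 CPM, MLANA (melan-A) at 556 ± 36.9 against 1.24 ± 1.36 CPM and SLC45A2 at 368 ± 4.58 against 3.11 ± 0.479 CPM. Of 32 pigmentation genes 29 were higher and 1 lower, also when adjusted over the list alone. The median was 3.11, or 2.85 with genes at 0 set to their bound (camera adjusted p = 2.1e-08, and adjusted p = 0.0333 with an estimated correlation). MITF was at 691 ± 15.2 against 33.4 ± 3.11 CPM (log2 4.33), and SOX10 at 446 ± 29.5 CPM against 1 count in all HEMa-LP libraries, a ratio of 1441 with a counting interval of 258 to 56906. TFAP2C was higher by 3.05, and the survival gene BCL2A1 was at 175 ± 10.4 CPM against 2 counts. Of 22 lineage regulators 16 were higher and 5 lower, also when adjusted over the list alone (median 3.14, camera adjusted p = 0.00175, and adjusted p = 0.0641 with an estimated correlation).

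Most tested fibroblast markers were far higher in the HEMa-LP libraries. FN1 (fibronectin), a matrix gene outside the fibroblast list, was at 5857 ± 219 CPM in HEMa-LP and 209 ± 25.7 CPM in control M14. COL1A2 was at 838 ± 53.5 CPM against 1 count, GREM1, a BMP antagonist gene, at 412 ± 43.0 CPM against none, and THY1 at 308 ± 10.7 against 0.373 ± 0.384 CPM. Of 18 tested fibroblast markers 17 were lower in control M14 and 1 higher, also when adjusted over the list alone (median -4.57, camera adjusted p = 1.7e-06, and adjusted p = 0.0404 with an estimated correlation). Of 25 fibroblast markers 11 reached 20 CPM in every HEMa-LP library, against 3 in control M14 and 5 in the knockout-labelled group, and of 32 pigmentation genes 13, 28 and 23 did so. Other markers, singled out after their values were seen, did not follow: in HEMa-LP, COL3A1 was at 1.82 ± 0.808 CPM, DCN at 6.99 ± 3.29 CPM and LUM at no count, while the melanocyte genes PAX3 and KIT were at 77.3 ± 10.7 and 33.7 ± 3.40 CPM. Of 3 tested keratinocyte markers KRT10 and PERP were higher in control M14, by 0.42 and 0.59, and DSP was lower (log2 -3.78), with the same counts adjusted over the list alone (median 0.42, mean -0.93, no camera test). KRT14, a basal keratinocyte gene also singled out, had no count in any of the 9 libraries.

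**Figure D4:**
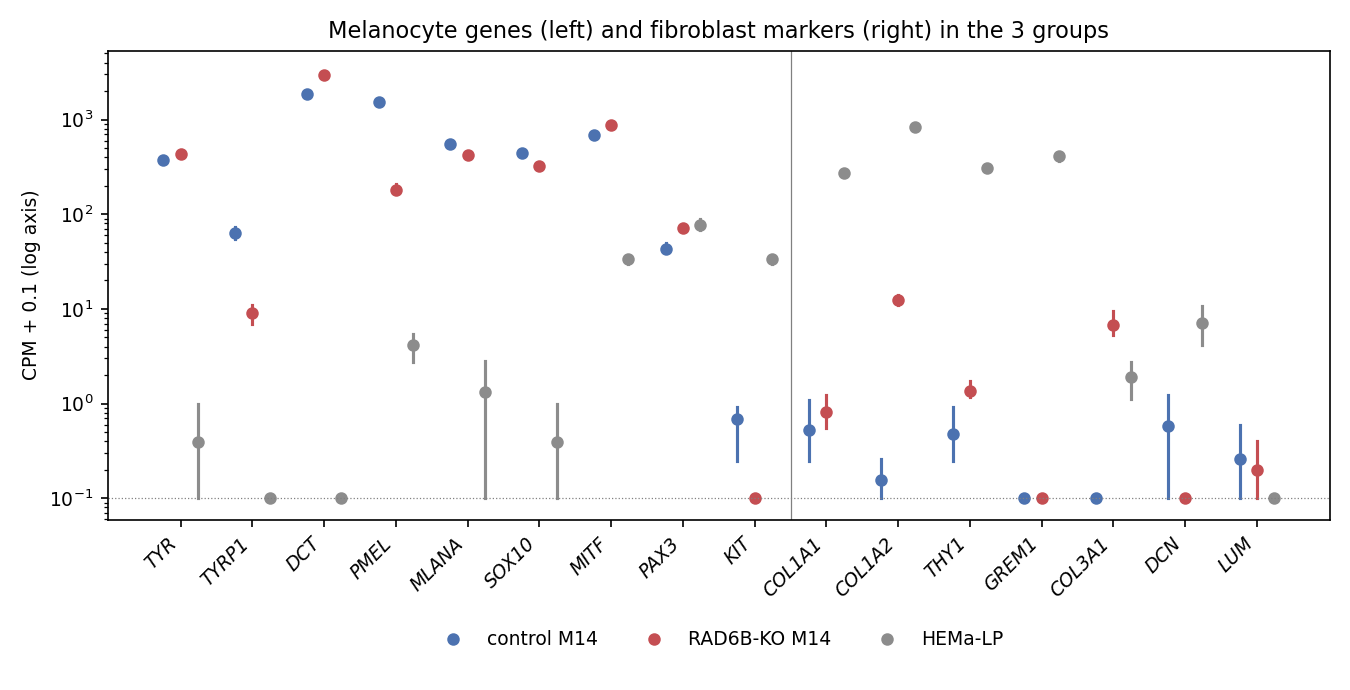
Levels of 9 melanocyte genes (left) and 7 fibroblast markers (right) in control M14, knockout-labelled M14 and HEMa-LP, as CPM plus 0.1 on a log axis (points are group means and lines run from the lowest to the highest of 3 libraries). TYR, DCT, PMEL, MLANA and SOX10 are high in both M14 groups and near 0 in HEMa-LP, while COL1A1, COL1A2, THY1 and GREM1 are high in HEMa-LP.

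The same direction held for neighbouring programmes. Of 28 invasive state genes 22 were lower in control M14 and 3 higher (median -2.03, camera adjusted p = 1.1e-05, and adjusted p = 0.0356 with an estimated correlation). Of 24 YAP and TEAD targets 20 were lower and 3 higher (median -2.20, adjusted p = 1.1e-05, and 0.0356 as adjusted p with an estimated correlation). CTGF and CYR61, the standard YAP target genes, were at 692 ± 70.9 and 847 ± 158 CPM in HEMa-LP against 0.455 ± 0.234 and 2.52 ± 0.209 CPM, and THBS1 differed by -8.66, IGFBP3 by -6.75 and CRIM1 by -5.64. Of 40 matrix genes 28 were lower and 8 higher, with VCAN at -4.22 and ALCAM at -4.45 (camera adjusted p = 3.4e-04, and adjusted p = 0.0404 with an estimated correlation). Of 25 epithelial-mesenchymal transition genes 17 were lower and 8 higher, with the collagenase gene MMP1 at -9.74 and COL1A1 at -9.29 (camera adjusted p = 0.0124, and adjusted p = 0.0889 with an estimated correlation). Of 27 p53 targets 19 were lower and 4 higher (camera adjusted p = 8.8e-04, and adjusted p = 0.0644 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, was at 852 ± 105 CPM in HEMa-LP and 48.6 ± 10.7 CPM in control M14, and PHLDA3, ZMAT3 and TRIAP1 differed by -7.20, -2.78 and -2.04. The counts of these 5 lists were the same adjusted over the list alone.

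Proliferation genes were higher in control M14 than in HEMa-LP. MCM2 was at 221 ± 13.2 against 13.1 ± 1.98 CPM and the flap endonuclease gene FEN1 at 208 ± 12.3 against 28.0 ± 5.20 CPM, while MCM7 and the maintenance methyltransferase gene DNMT1 were higher by 3.08 and 1.84. Of 43 replication genes 37 were higher and none lower, or 38 and none adjusted over the list alone (median 1.70, camera adjusted p = 1.4e-07, and adjusted p = 0.0333 with an estimated correlation). Of 42 mitosis genes 37 were higher and 2 lower, also when adjusted over the list alone, with UBE2C at 3.11, PRC1 at 3.28 and AURKB at 3.00 (median 2.31, camera adjusted p = 1.4e-07, and adjusted p = 0.0333 with an estimated correlation). PTTG1 was higher by 3.30 but has near-identical copies. Of 28 Fanconi genes 14 were higher and 5 lower, with UBE2T at 3.51, FANCI at 3.04, FANCD2 at 2.94 and BLM at 2.81 (camera adjusted p = 0.0378, and adjusted p = 0.122 with an estimated correlation). Cholesterol genes were higher for 17 of 23 and lower for 3, with EBP at 1.97, FDFT1 at 1.47 and INSIG1 at 1.32 (camera adjusted p = 0.00392, and adjusted p = 0.0791 with an estimated correlation). Oxidative phosphorylation genes were higher for 37 of 47 and lower for 3, with SDHB at 3.52, ATP5G3 at 2.29 and ATP5B at 2.18 (camera adjusted p = 4.8e-05, and adjusted p = 0.122 with an estimated correlation). The counts of the last 3 lists were the same adjusted over the list alone.

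Of 22 cancer-testis antigen genes with a row in the count table, 5 had counts enough for a test. In control M14 MAGEA12 was at 70.0 ± 10.8 CPM, CSAG1 at 60.9 ± 5.89 CPM and MAGEA3 at 17.8 ± 2.09 CPM, each with no count in HEMa-LP, at least 75.2-fold, 65.3-fold and 19.1-fold higher. PRAME was at 253 ± 9.18 against 40.6 ± 3.84 CPM. All 5 tested members were higher, also when adjusted over the list alone (median at bound 4.25, camera adjusted p = 8.5e-04, and adjusted p = 0.0641 with an estimated correlation). Of these, 4 had no count in HEMa-LP and passed the filter only through control M14. Their direction was thus fixed in advance, and the camera p rests largely on it. MAGEA and CSAG genes have near-identical copies. Cytosolic ribosomal protein genes were lower in control M14 for 37 of 56 and higher for 15, also when adjusted over the list alone (camera adjusted p = 0.00230, and adjusted p = 0.381 with an estimated correlation). RPS28 was at 6228 ± 742 CPM in HEMa-LP against 48.8 ± 5.74 CPM, and RPS27, RPS3A and RPL3 differed by -7.48, -6.76 and -4.12. These genes have many pseudogenes, as does UQCRB, a complex III gene at 1050 ± 72.2 against 58.4 ± 7.03 CPM, and the ribosomal list could not be tested without genes that have pseudogene copies.

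Canonical Wnt targets were higher in control M14 than in HEMa-LP for 17 of 26 and lower for 5, with the same counts adjusted over the list alone. LEF1 was at 63.5 ± 2.97 CPM against no count, at least 68.2-fold higher, MYC was higher by 2.01 (adjusted p = 2.8e-11) and BIRC5 by 2.10. CCND1 ran the other way, at 2973 ± 145 CPM in HEMa-LP and 173 ± 6.20 CPM in control M14 (log2 -4.14, adjusted p = 1.7e-33). AXIN2 was at 8.96 ± 1.14 against 3.60 ± 2.57 CPM (log2 1.23, adjusted p = 0.0138) and no longer passed without HEMa-LP replicate 3 (adjusted p = 0.104) or with DESeq2 (adjusted p = 0.0509), and over all alternatives its adjusted p ran from 0.00548 to 0.104. Camera called the list (median 1.46, adjusted p = 0.0335, and adjusted p = 0.226 with an estimated correlation). That call was also lost without control M14 replicate 1 (adjusted p = 0.0594) or 3 (0.0602) and without HEMa-LP replicate 1 (0.0637) or 2 (0.0691).

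Other Wnt genes separated both groups without a call for their lists. WNT1 was at 75.7 ± 6.24 CPM in control M14 with no count in HEMa-LP, at least 81.3-fold higher, and CTNNB1 was higher by 1.62 (adjusted p = 2.6e-19). The receptor gene FZD7 was higher by 4.87 and FZD2 lower, at -2.66. The noncanonical ligand WNT5B was at 385 ± 51.2 CPM in HEMa-LP and at 2 counts in control M14, and WNT5A at 130 ± 14.2 against 7.08 ± 1.53 CPM. NFATC2 and NFATC4, genes of calcium-responsive transcription factors, moved oppositely, at 543 ± 13.2 CPM against 3 counts and at 1 count against 126 ± 18.3 CPM. Among antagonists SFRP1, CXXC5, APCDD1 and FRZB were lower in control M14, the last with no count there and 30.9 ± 7.26 CPM in HEMa-LP. Of 32 ligands, receptors and transducers 17 were higher and 9 lower (camera adjusted p = 0.330), and of 14 antagonists 4 and 8 (adjusted p = 0.123), the same adjusted over the list alone. Of 28 noncanonical members 9 were higher and 13 lower (adjusted p = 0.330), or 10 and 14 adjusted over the list alone. RAD6 pathway genes were higher for 9 of 22 and lower for 10, also when adjusted over the list alone (adjusted p = 0.889), with PCNA at 2.35, MAD2L2 at 2.04, POLH at -1.39 and POLK at -2.49.

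Besides DCT, genes without a count in HEMa-LP and far higher in control M14 included CD74 (at least 944-fold), the osteopontin gene SPP1 (at least 793-fold), FXYD3 (at least 670-fold), the connexin gene GJB1 (at least 519-fold), ITIH5 (at least 299.6-fold), LCP1 (at least 227-fold) and TMEM163 (at least 123-fold). Besides COL1A2 and GREM1, genes far lower in control M14 included the G protein regulator gene RGS4 (at least 5386-fold), the metalloproteinase gene PAPPA (at least 3810-fold), HSPB7 (at least 2660-fold), VGLL3 (at least 1755-fold) and the stanniocalcin gene STC1, at 1251 ± 103 CPM in HEMa-LP and 3 counts in control M14. In all, 8741 of 11503 tested genes (76.0%) passed, 4539 higher and 4202 lower, and 5948 with an absolute log2 fold change of at least 1. Libraries did not overlap for 8959 genes (77.9%), where chance gives 10%. Camera called 16 lists, of which 7 held with an estimated correlation. Of the genes tested here 8282 passed both here and among the 9616 of the authors' deposited table, all with the same sign.

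Knockout-labelled M14 cells were also compared with HEMa-LP, under the same confounding of cell type with medium and depth. Interferon response genes had the smallest camera p of the lists. IFI6 was at 5096 ± 234 against 31.4 ± 8.34 CPM, BST2 (tetherin) at 877 ± 23.1 against 3.31 ± 1.98 CPM and MX1, a dynamin-like antiviral GTPase gene, at 596 ± 58.1 against 10.9 ± 4.35 CPM. IFITM2 was the exception at 1.48 ± 1.02 against 393 ± 46.8 CPM, with the uncertainty of overlapping annotation given above. Of 39 tested members 37 were higher and 1 lower, also when adjusted over the list alone (median 3.39, camera adjusted p = 2.6e-09, and adjusted p = 0.0447 with an estimated correlation). In control M14 against HEMa-LP the list had 14 members higher and 12 lower of 34, or 15 and 14 adjusted over the list alone (camera adjusted p = 0.967). The difference between these comparisons is the rise in the knockout-labelled libraries over control M14 described above.

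Proliferation genes in the knockout-labelled libraries were not separated from HEMa-LP as a list. Of 41 replication genes 11 were higher, 11 lower and 19 did not pass, or 10 and 10 adjusted over the list alone (median -0.17, camera adjusted p = 0.557). The S phase checkpoint gene CLSPN, RRM1, RRM2 and MCM4 were lower in the knockout-labelled libraries, at log2 differences of -2.08, -1.21, -2.25 and -1.78. Of 42 mitosis genes 9 were higher, 7 lower and 26 did not pass, also when adjusted over the list alone (median 0.08, camera down, adjusted p = 0.815). TOP2A, CDC25B and CENPE differed by -1.32, -1.38 and -1.49, while PTTG1, which has near-identical copies, was higher. Of 26 Fanconi genes 6 were higher and 5 lower, also when adjusted over the list alone (median -0.02, mean 0.09, camera adjusted p = 0.815), with FANCB at 2.40, FANCL at 1.93, FANCI at 1.39 and BRCA1 at -1.28. RAD6 pathway genes were higher for 10 of 22 and lower for 3, or 9 and 3 adjusted over the list alone (adjusted p = 0.449), with HLTF at 1.13, MAD2L2 at 1.15 and POLH at -1.99. A p that misses the threshold does not show that levels were equal.

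Pigmentation and lineage genes remained above the HEMa-LP level. DCT was at 2942 ± 205 CPM against none, at least 3158-fold higher, TYR (tyrosinase) at 438 ± 33.9 CPM against 1 count, and MLANA and GPNMB were higher by 8.37 and 3.80. Of 29 tested pigmentation genes 26 were higher and 1 lower, or 26 and 2 adjusted over the list alone (median 1.95, camera adjusted p = 1.1e-06, and adjusted p = 0.0503 with an estimated correlation). MITF was higher by 4.69, SOX10 was at 325 ± 18.3 CPM against 1 count, and the neuregulin receptor gene ERBB3 was higher by 5.86. Of 22 lineage regulators 16 were higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.00240, and adjusted p = 0.271 with an estimated correlation). All 5 tested cancer-testis genes, of 22, were higher, also when adjusted over the list alone, with PRAME at 2.77 (median at bound 3.63, camera adjusted p = 5.0e-04, and adjusted p = 0.116 with an estimated correlation). Again 4 of them had no count in HEMa-LP, so their direction was fixed by the filter.

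Most tested fibroblast, invasive state and YAP genes lay below the HEMa-LP level. COL1A2 was at 12.2 ± 1.46 against 838 ± 53.5 CPM, COL1A1 at 0.720 ± 0.372 against 273 ± 19.2 CPM and GREM1 at no count against 412 ± 43.0 CPM. Of 19 fibroblast markers 15 were lower and 3 higher (median -4.41, camera adjusted p = 4.2e-05, and adjusted p = 0.0556 with an estimated correlation). Of 29 invasive state genes 20 were lower and 4 higher (median -1.43, camera adjusted p = 5.0e-04, and adjusted p = 0.0682 with an estimated correlation), with CTGF at -10.51 and THBS1 at -8.38. Of 23 YAP and TEAD targets 19 were lower and none higher, or 19 and 1 adjusted over the list alone, with the receptor kinase gene AXL at -4.05 (camera adjusted p = 6.5e-06, and adjusted p = 0.0503 with an estimated correlation). Of 27 p53 targets 21 were lower and 4 higher, with CDKN1A at 38.5 ± 4.70 against 852 ± 105 CPM (camera adjusted p = 6.1e-05, and adjusted p = 0.131 with an estimated correlation). Ribosomal protein genes were lower for 34 of 56 and higher for 13, or 35 and 13 adjusted over the list alone (camera adjusted p = 5.0e-04, and adjusted p = 0.297 with an estimated correlation), with RPLP0 at -3.71, and their pseudogenes leave these values uncertain. The other counts were the same adjusted over the list alone. Of 3 keratinocyte markers PERP differed by 0.88 and DSP by -3.35, also when adjusted over the list alone.

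Among Wnt genes, the knockout-labelled libraries held more CTNNB1 than HEMa-LP, 488 ± 11.8 against 249 ± 23.7 CPM (log2 0.96, adjusted p = 3.8e-12). LEF1 was at 33.3 ± 6.14 CPM against none, at least 35.8-fold higher, MYC was higher by 1.09 and CCND1 was at 158 ± 13.7 against 2973 ± 145 CPM. AXIN2, at low levels in both groups, was lower in the knockout-labelled libraries in the authors' deposited table, at log2 -1.82 (false discovery rate 0.0438). A value this near the threshold, at such low levels and under a model that is not given, does not settle the direction. The receptor gene TNFRSF19 was at 113 ± 4.33 CPM against 1 count, and APCDD1 at no count, at least 398-fold lower. Of 26 canonical targets 17 were higher and 6 lower (camera adjusted p = 0.0609), and camera called the list without genes that have pseudogene copies (adjusted p = 0.0318). The receptor gene FZD7 and PYGO1 were higher by 4.30 and 3.48, and RSPO3, a ligand that amplifies Wnt signals, was at 2 counts against 23.7 ± 4.56 CPM. WNT5B was at 3 counts against 385 ± 51.2 CPM, NFATC2 at 791 ± 46.1 CPM against 3 counts, and PLCB3 differed by -2.73. FRZB was at 2 counts against 30.9 ± 7.26 CPM, and CXXC5 and CHD8 differed by -3.29 and -1.21. Ligands, receptors and transducers were higher for 15 of 29 and lower for 8 (adjusted p = 0.263), antagonists for 7 and 7 of 15 (adjusted p = 0.606), and noncanonical members for 10 and 12 of 29 (median 0.03, camera down, adjusted p = 0.654). All these counts were the same adjusted over the list alone.

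The largest fitted differences repeated many of those of the parental line. Besides DCT, genes without a count in HEMa-LP and far higher in the knockout-labelled libraries included SPP1 (at least 3376-fold), CD74 (at least 3333-fold), ITIH5 (at least 865-fold), FXYD3 (at least 778-fold), GJB1 (at least 308-fold), the acute phase protease inhibitor gene SERPINA3 (at least 293-fold) and TFAP2B (at least 249.5-fold). Genes far lower included IGFBP2, an insulin-like growth factor binding protein gene at 1.13 ± 0.367 against 18995 ± 1616 CPM, RGS4, GREM1, HSPB7 (at least 2480-fold), the pentraxin gene PTX3 (at least 1504-fold), NFATC4 (at least 756-fold) and COX7A1 (at least 736-fold). In all, 8043 of 11483 tested genes (70.0%) passed, 4261 higher and 3782 lower, and 5117 with an absolute log2 fold change of at least 1. Libraries did not overlap for 8458 genes (73.7%), where chance gives 10%. Camera called 9 lists, of which only interferon response held with an estimated correlation. Of the genes tested here 7633 passed both here and among the 8876 of the authors' deposited table, all with the same sign.

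The fold changes of knockout-labelled over control M14 and of HEMa-LP over control M14 were then compared across 12857 genes. Genes that differed between the melanoma line and HEMa-LP moved on balance in the direction of the HEMa-LP level, including replication and mitosis genes such as MCM7, AURKB and PRC1 that were lower in both. Among 11040 genes tested in both comparisons, 1962 were higher in both the knockout-labelled and HEMa-LP libraries than in control M14, where independent lists would share 1157, and 2433 were lower in both, against 1515. Opposite changes were fewer, at 718 (1401 for independent lists) higher and 559 (1251) lower in the knockout-labelled libraries. The covariance was 0.880, against 0.0273 from shared control libraries alone in 100 simulations (0.0249 to 0.0301), a difference of 0.853. Pearson's r across genes was 0.376 and Spearman's rho 0.412, and genes are not independent replicates. In the simulations r was 0.320, but there the groups differed by noise alone. That value is therefore no baseline for the r of these data, and only the covariance is compared with the simulations. The 3 control libraries cannot be divided into parts of at least 2, so part of the excess overlap may come from the shared controls.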

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

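The alternatives chosen only after the data were seen were thinning M14 libraries to the HEMa-LP depth and leaving out genes with pseudogene copies. Low depth in HEMa-LP, with a floor of 0.931 CPM, limits every comparison with those libraries. Most named genes were chosen for large changes or small adjusted p in these same data, so their stability was largely fixed by that choice. A setting that filtered a gene out gave no value for it. Of 5479 values for 361 named gene results under the alternatives, 5472 kept direction and side of the threshold, 7 kept direction but no longer passed, and none reversed. Those 7 were CSAG1 between the M14 groups (adjusted p = 0.0666 with DESeq2, 0.134 without control M14 replicate 1 and 0.172 without knockout-labelled replicate 2), MAGEA3 between the M14 groups (0.0512 without control M14 replicate 2), PERP between the M14 groups (0.0502 without knockout-labelled replicate 3), and AXIN2 in control M14 against HEMa-LP (0.0509 with DESeq2 and 0.104 without HEMa-LP replicate 3). The cause was not tested.

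Counts of genes past the threshold ran from 6984 (5 CPM filter) to 7931 (all 9 libraries in a single fit) for the M14 groups, against 7601, and from 7229 to 7397 with a library left out. With DESeq2, 6848 of those 7601 genes passed, all with the same sign. For control M14 against HEMa-LP the counts ran from 7803 to 8570 with a library left out, and were 7325 after thinning and 7149 without genes with pseudogene copies. For the knockout-labelled group against HEMa-LP they ran from 7212 to 7832 with a library left out, and were 6749 and 6628 in those added settings. A minimum absolute log2 fold change of 1 lowered the counts by construction. It left 3416 genes between the M14 groups (2025 higher, 1391 lower), 2792 lower in control M14 against HEMa-LP, and 5117 in the knockout-labelled group against HEMa-LP (2272 lower).

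Camera with an estimated correlation called 4 lists between the M14 groups, 7 in control M14 against HEMa-LP and 1 in the knockout-labelled group against HEMa-LP, in place of 13, 16 and 9. Between the M14 groups, the estimate for some lost lists lay below the preset 0.01. It was -0.0295 for Fanconi, -0.00872 for pigmentation and -0.0698 for fibroblast genes, so a higher inter-gene correlation does not account for those losses. For others it lay above, at 0.0404 for oxidative phosphorylation and 0.0226 for matrix genes. That does not show that correlation cost them the call. The estimate for interferon response, -0.00974, also lay below the preset, yet its unadjusted camera p rose from 3.6e-17 to 5.8e-04. Both runs therefore differ by more than the correlation of a list, and a lost call is no sign of correlated genes. Fry called 26 lists between the M14 groups and 26 in the knockout-labelled group against HEMa-LP, by construction, since it does not compare a list with other genes. With a library left out camera called 13 lists between the M14 groups every time, 14 to 16 in control M14 against HEMa-LP and 8 or 9 in the last comparison. The cancer-testis list had too few tested members for camera without some M14 libraries. The covariance of the fold changes over control M14 less its simulated value, 0.853, was 0.850 with DESeq2 size factors, 0.873 with the 5 CPM filter, 1.17 with a prior count of 0.5, 0.895 without genes with pseudogene copies, and 0.838 to 0.874 with a library left out. For the covariance the cause was not tested.

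With the replicate number as a block, 7508, 8697 and 8035 genes and 13, 16 and 9 lists passed, that covariance was 0.853 as without the block, and UBE2B differed by 0.37, 0.72 and 1.10. Same-numbered libraries did not deviate together, so the numbers do not pair the samples. The correlations across genes were 0.0686, 0.0103 and -0.0526 between the M14 groups, -0.0267, -0.00138 and -0.0141 for control M14 and HEMa-LP, and 0.0328, -0.00710 and -0.0291 for the knockout-labelled group and HEMa-LP. The best match carried the same number only for number 1 in the first and last of these. The first and second sequencing run were not tested apart, because they are not separate columns, and the other count table was not run, because its M14 columns are identical.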

Other observations

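Several gene lists fell outside the rule for the lists described, and their genes were chosen after their values were seen. Between the M14 groups, DUSP6, which encodes a phosphatase of ERK, rose by 1.34 in the knockout-labelled libraries and SPRY2 by 1.76, and in the MAPK list 10 of 21 members rose and 4 fell (camera adjusted p = 0.220). Hypoxia and glycolysis genes parted, since NDRG1 rose by 1.77 while the glycolytic enzyme genes ENO1, PKM and GPI changed by -1.23, -1.32 and -1.38 (13 higher and 15 lower of 34, median 0.07, mean 0.20, camera down, adjusted p = 0.898). In the stress response list the chaperone gene HSP90B1 rose by 1.11 and the amino acid transporter gene SLC3A2 changed by -1.74 (15 higher and 17 lower of 37, or 16 and 17 adjusted over the list alone, adjusted p = 0.770). Among apoptosis regulators BIRC3 and BIRC2 rose by 5.08 and 1.47 and the cytochrome c gene CYCS by 1.25 (11 higher and 8 lower of 32, adjusted p = 0.770).

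Among YAP and TEAD targets CRIM1 and IGFBP3 rose by 2.52 and 2.77 and DLC1 changed by -1.49 (9 higher and 4 lower of 22, adjusted p = 0.323). Metallothionein genes, which share near-identical sequence, rose for 5 of 6, with MT1E at 0.84 and MT2A at 0.26 (adjusted p = 0.0836). The p53 targets went both ways, with ZMAT3 at 1.01, CYFIP2 at -3.37, FDXR at -1.03 and GADD45B at -1.24 (7 higher and 9 lower of 25, adjusted p = 0.659). Ribosomal protein genes did too, with RPS24 at 0.87 and RPLP1 at -0.77 (11 higher and 21 lower of 56, adjusted p = 0.323). Among melanoma antigens MAGEA12 changed by -0.71 (2 higher and 3 lower of 7, or 3 and 3 adjusted over the list alone, adjusted p = 0.898). The other counts were the same adjusted over the list alone, except that 1 metallothionein gene then fell. In control M14 against HEMa-LP, the NF-kB list had a median of 0.00 but a mean of -1.21 (camera down, adjusted p = 0.555).

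Of the tests that follow, those on mitochondrial rRNA, on depth for melanocyte genes and on fibroblast markers were chosen only after the result was seen. The mitochondrial rRNA genes had no count in HEMa-LP. Lower depth is argued against, because 34524 counts would have been expected in the shallowest HEMa-LP library at the control M14 share. The near-copies MTRNR2L were at least 74.0 times higher in every HEMa-LP library than in any M14 library. That value goes with a candidate explanation, another reference or handling of reads with several matches for HEMa-LP, which remains a hypothesis. Lower mitochondrial RNA content alone was expected to lower MTRNR2L as well. As the only cause it is argued against, because MTRNR2L was higher, at 6683 ± 395 CPM against 83.9 ± 0.161 CPM in control M14. As a cause beside read handling it cannot be told apart and stays open. The rRNA genes and MTRNR2L together stood in every HEMa-LP library at no more than 0.224 times the level of any M14 library, but reads lost for having several matches would lower that sum too.

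Melanocyte genes such as TYR, DCT and TYRP1 lay near 0 in HEMa-LP. Lower depth is argued against, because a median of 221 counts was expected over 7 pigmentation genes that had 3 or fewer. Random loss of gene models is argued against, because 11 of 45 pigmentation and lineage genes (24.4%) of at least 20 CPM in control M14 lay under 1 CPM in HEMa-LP, against 136 of 6732 others (2.02%), an odds ratio of 15.7 (95% interval 7.01 to 32.5, two-sided Fisher's exact p = 1.9e-09). Fibroblasts in the culture cannot be told apart from a change of the melanocytes themselves, because 11 of 25 markers reached 20 CPM in every HEMa-LP library while COL3A1, DCN and LUM were low and PAX3 and KIT were present. Several of these markers are also matrix genes that other cell types express, so the state or identity of the HEMa-LP cells stays open.

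Fold changes of neighbouring genes moved together between the M14 groups. A chance order of genes is argued against, because the SD of block medians was 0.308, against a mean of 0.107 and a highest value of 0.128 in 1000 shuffles. Copy-number differences may contribute to blocks such as those on chromosome 22. Of 5807 genes that passed with an absolute log2 fold change of at least 0.5, 4831 (83.2%) kept that size and sign after the block median was subtracted. Shifts shared by a whole block therefore do not account for the size of most of these changes. Block medians ran only from -0.91 to 0.65, so the subtraction could take little from a large change. Gains or losses smaller than a block were not removed by it, so copy number as the main source is neither shown nor excluded. Loss of RAD6B, clonal differences and copy number stay open, since a single knockout-labelled line was compared. No other cause of the pattern along the chromosomes was tested, and neither was its relation to how densely genes lie.

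The 10 splits of each pair of groups into 3 and 3 libraries are too few for a share under 0.05. Only 1 split of the 10, the real one, gave as many genes in each comparison, with 7601, 8741 and 8043 genes against at most 0 in any other split. Every other split mixes both groups on each side, so the difference between groups widens the spread within a side. Low gene counts there follow from that, and no conclusion is drawn from them. For lists it was also 1 of 10 each time, with 13, 16 and 9 lists against at most 10, 13 and 8.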
